A study of Mus musculus with 5 samples.

How the data were processed

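The series holds RNA sequencing of primary tumors grown from B16F1 cells, a murine melanoma line derived from the B16 tumor of C57BL/6 mice, and from B16F1 cells made to overexpress the chemokine CXCL5. The cells were injected into the skin of the flank of C57BL/6J mice, and tumors were excised at a volume of 250 to 350 mm³ and snap frozen, per the labels. There were 3 libraries of B16F1 tumors and 2 of B16F1-CXCL5 tumors. Per the labels' protocols, RNA integrity numbers lay between 8.7 and 9.5 with a median of 9.4, and the poly(A) fraction was made into strand-specific libraries with the TruSeq Stranded mRNA kit and sequenced on a HiSeq2000. Whole tumors were sequenced, so the values mix melanoma cells with the host cells of the tumor and any adjoining skin.

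The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to library size) for 23284 genes in the 5 libraries. Per the submitters' processing notes, the tools were FastQC 0.10.1, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.1.9 and Cufflinks 2.2.1, with the mouse build GRCm38 (mm10). The gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. The column of each library was taken from its title, and no column belonged to another sample. FPKM values divide by transcript length and by library size, so counts per gene were not analysed here and no count model was used. Cufflinks divides the fragments of genes with near-identical copies by a model, so values of such genes are uncertain, and values of genes shorter than a sequenced fragment rest on a very small effective length.

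No total of fragments per library was used here. The low FPKM values fall into steps that scale with transcript length, and the size of the first step estimates the value of 1 fragment. Over 3057 genes with a single annotated transcript of 800 to 6000 nt, with 200 nt subtracted as an assumed fragment length, the steps imply 26600000, 26800000 and 28600000 fragments for B16F1 libraries 1, 2 and 3. The same estimate is 27500000 and 28200000 for B16F1-CXCL5 libraries 1 and 2. These depths are estimates that rest on the assumed fragment length, and the GENCODE M21 annotation of GRCm38 gave the transcript lengths and all coordinates. The share of bit-identical values between any pair of libraries was at most 0.12% of tested genes, so every library was counted as its own sample.

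Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and an intensity trend. Genes with an FPKM of at least 1 in at least 2 of the 5 libraries entered the test, which left 12533 genes. The Benjamini-Hochberg adjusted p had to be under 0.05. Log2 fold changes are B16F1-CXCL5 minus B16F1 on the log2(FPKM + 1) scale, which understates the change of genes with low values, and folds are ratios of the mean FPKM of the groups. Errors are SD over the 3 or 2 libraries of a group, and SE for log2 fold changes. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples. They also do not say whether the B16F1-CXCL5 cells were a single clone, so a difference between the groups may belong to CXCL5 or to a clone of cells. An exact two-sided permutation test over the 10 splits of the 5 libraries cannot give a p below 0.1 and was used for single values.

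Before the data were examined, 35 gene lists with 706 symbols were fixed, for host cell types, the melanocyte lineage, CXCR2 signalling and pathways. Of these symbols, 697 were found in the table, 14 of them under an older name, and 9 were not found and were not analysed here, Ly6g among them. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. Each was also tested with camera's estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. The score of a list in a library is the mean log2(FPKM + 1) of its tested members. The 4 other lists had fewer than 5 members over the filter and were tested only without it.

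Named genes were chosen by a rule fixed before the data were examined. It takes Cxcl5, then the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, leaving out symbols of predicted genes, RIKEN clones, microRNA, small nucleolar and ribosomal RNA genes and antigen receptor segments. Where fewer than 5 genes passed in a direction, the 10 smallest unadjusted p-values in that direction are named as not passing. It adds up to 4 members with the smallest p of each list that passed, up to 2 members with the highest mean FPKM of each other list, and 26 genes fixed by name. Genes named outside this rule are said to be so where they appear, and some genes that the rule takes are not reported here.

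The procedure was tested on simulated data with the spread of these libraries, 12533 genes and 10 simulations. The simulated genes varied independently of one another, and changed genes and lists were drawn only from genes above a minimum mean value. The procedure called 28.4% of genes changed by 1.5-fold, 76.2% by 2-fold, 97% by 4-fold and 98.6% by 8-fold. It also called 0.06% of unchanged genes. Over the 10 simulations 500 genes were changed at each fold, with spread drawn from limma's own fitted model. The real test called only 17 genes, so its p threshold was stricter, and the shares of changed genes called may be too high for the real data. A simulated list moved by 0.5 on the log2 scale was called in 10 of 10 simulations, and 0 of 290 unmoved lists were called. Genes of these lists were uncorrelated, whereas camera estimated correlations of 0.256 for the real neutrophil markers and 0.764 for the real fibroblast genes. The simulation therefore cannot show how often lists of correlated genes are called falsely.

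The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter of mean FPKM of at least 3, rescaling to the same sum or the same upper quartile, quantile normalization, no intensity trend, library weights, replicate numbers as a block, leaving out each library in turn, and both other list tests. Leaving out the small RNA genes, and leaving Cxcl5 out of the CXCR2 list, were added after the data were seen. The figures and the depth estimate were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.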

Results

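Gene expression was measured by RNA sequencing in primary melanomas of mice, with 3 libraries of B16F1 tumors and 2 libraries of tumors from B16F1 cells that overexpress CXCL5, a chemokine that attracts neutrophils through the receptor CXCR2. The comparison asks what CXCL5 overexpression in the melanoma cells changes in the primary tumor and the host cells within it. Each library had between 17111 and 17513 genes with an FPKM above 0 and between 12029 and 12421 genes with an FPKM of at least 1. The depth implied by the steps of the low values was 26600000 to 28600000 fragments per library, so depth was similar in both groups.

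Cxcl5 was expressed at a low level in B16F1 tumors and at a much higher level in both B16F1-CXCL5 tumors. The gene lies on chromosome 5 from 90759360 to 90761624 on the plus strand (GRCm38). Its FPKM was 1.86, 3.62 and 1.01 in the B16F1 libraries and 83.7 and 85.4 in the B16F1-CXCL5 libraries. The group means were 2.16 ± 1.33 FPKM (SD, n = 3) and 84.6 ± 1.19 FPKM (SD, n = 2), a ratio of 39.1. The log2 fold change was 4.84 with an SE of 0.33, and the limma adjusted p was 0.0163. The exact two-sided permutation p was 0.1, the smallest that 10 splits allow. With a pseudocount of 0.1 the adjusted p was 0.0556, and without B16F1 library 1 or either B16F1-CXCL5 library it lay between 0.0808 and 0.235. In all of these settings Cxcl5 stayed higher in the B16F1-CXCL5 libraries.

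**Figure D1:**
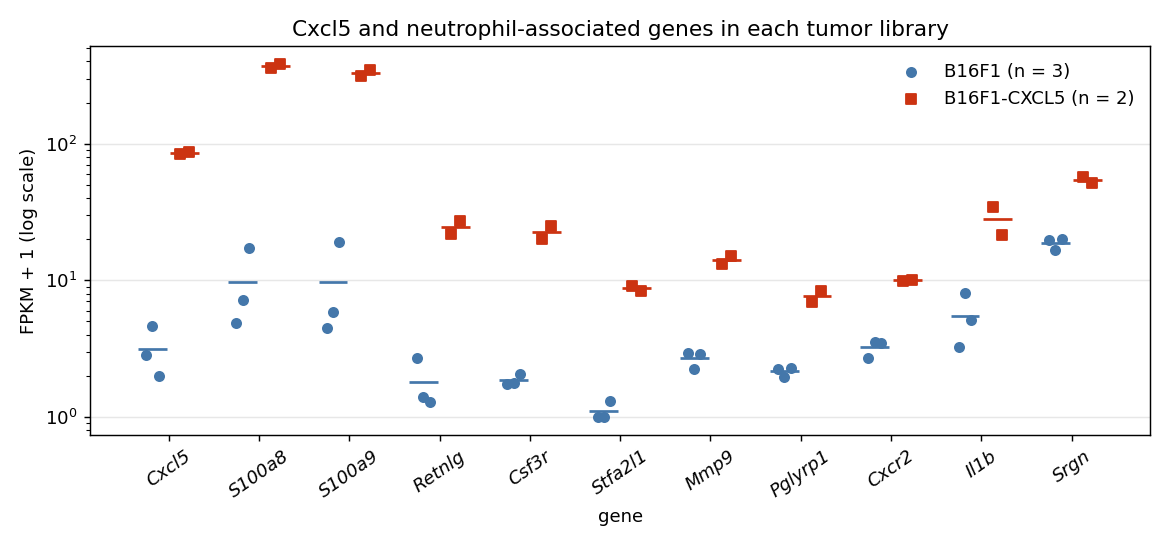
FPKM + 1 on a log axis for Cxcl5 and 10 genes expressed in neutrophils in each library, with circles for the 3 B16F1 tumors, squares for the 2 B16F1-CXCL5 tumors and horizontal lines at the group means. For each gene both B16F1-CXCL5 libraries lie above all 3 B16F1 libraries, and Cxcl5 lies at 83.7 and 85.4 FPKM against at most 3.62 FPKM. S100a9 and Il1b did not pass the threshold over all genes.

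Genes of neutrophils were the main group among those that rose in the B16F1-CXCL5 tumors. Of 12533 genes tested, 17 passed an adjusted p of 0.05 with limma, 16 higher and 1 lower, and 1124 had an unadjusted p under 0.05. Of the 17, 14 were not small RNA genes, all of them higher, and 8 of those 14 were on the list of neutrophil markers. The highest ratio of mean FPKM among them, leaving aside Stfa2l1, belonged to S100a8, a calcium-binding protein abundant in the cytosol of neutrophils. It went from 8.73 ± 6.60 FPKM (SD, n = 3) to 369 ± 18.4 FPKM (SD, n = 2), a ratio of 42.3, with a log2 fold change of 5.46, an SE of 0.51 and a limma adjusted p of 0.0403. That call was lost under 5 settings that kept every library, with adjusted p-values of 0.0535 and 0.0884 for pseudocounts of 0.5 and 0.1, 0.0568 at the same sum per library, 0.071 with a mean FPKM of at least 3 and 0.0945 without a filter. S100a8 lies on chromosome 3 from 90668978 to 90670035. S100a9, its partner in the calprotectin dimer, had 8.78 ± 8 and 329 ± 21.1 FPKM and did not pass, with a limma adjusted p of 0.0674. It passed with library weights (adjusted p = 0.0244), with replicate numbers as a block (adjusted p = 0.000268), without B16F1 library 3 (adjusted p = 0.00104) and without the small RNA genes (adjusted p = 0.0436), the last of these a setting added after the data were seen. The block leaves B16F1 library 3 without a partner, so it compares the same libraries as the setting without that library (log2 fold change 6.01 in both). Both S100a8 and S100a9 had their highest B16F1 value in library 3, at 16.2 and 18.0 FPKM, and that library also had the highest keratinocyte score of the 5, 5.25 against 3.83 to 4.39.

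Csf3r, the receptor for granulocyte colony-stimulating factor, had the smallest p of the genes that are not small RNAs. It went from 0.855 ± 0.1795 to 21.5 ± 3.68 FPKM, with a log2 fold change of 3.60, an SE of 0.15 and a limma adjusted p of 0.00195. Csf3r lies on chromosome 4 from 126024550 to 126044440. Retnlg, a resistin-like protein of neutrophils, rose from 0.803 ± 0.785 to 23.5 ± 3.96 FPKM (limma adjusted p = 0.033). Stfa2l1, a cystatin family gene, was listed at 0 in B16F1 libraries 1 and 2, at 0.309 FPKM in library 3, and at 8.03 and 7.39 FPKM in the B16F1-CXCL5 libraries (limma adjusted p = 0.00874). Its values are uncertain because the stefin A genes are close copies of one another. Mmp9, the gelatinase stored in neutrophil granules, rose 7.79-fold to 13.2 ± 1.39 FPKM (limma adjusted p = 0.0146). Pglyrp1, a peptidoglycan recognition protein of neutrophil granules, rose 5.71-fold to 6.64 ± 1.00 FPKM, and Cxcr2, the receptor of CXCL5, rose 4.01-fold from 2.24 ± 0.469 to 8.99 ± 0.110 FPKM. Their limma adjusted p-values were 0.0227 and 0.0364.

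Outside that list, 6 genes that are not small RNAs rose, Cxcl5 among them. Sorl1, a sorting receptor, rose 14.9-fold to 4.09 ± 0.518 FPKM. H2-Q10, a nonclassical MHC class I gene, rose 9.62-fold to 4.16 ± 0.254 FPKM, a value that is uncertain because the genes of the H2-Q cluster share sequence. Cd33, a receptor of myeloid cells, rose 5.62-fold to 3.43 ± 0.245 FPKM. Srgn, the proteoglycan of leukocyte granules, rose 3.02-fold from 17.7 ± 1.84 to 53.5 ± 3.85 FPKM, and Art5, an ADP-ribosyltransferase, rose 2.64-fold to 15.3 ± 1.21 FPKM. Cd33, Srgn and Art5 were outside the naming rule and were named after their values were seen, to complete the called genes. The limma adjusted p-values of these 5 genes lay between 0.0163 and 0.033.

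The other 3 called genes were small RNA genes, which a poly(A) library does not target. Snord1b had 28.99, 27.2 and 26.1 FPKM in the B16F1 libraries and was listed at 0 in both B16F1-CXCL5 libraries. Scarna8 was listed at 0 in all 3 B16F1 libraries and had 6.83 and 6.92 FPKM in the B16F1-CXCL5 libraries. Mir3062 was likewise listed at 0 in the B16F1 libraries and had 6.50 and 6.82 FPKM in the others. Snord1b and Mir3062 were named after their values were seen. Their annotated lengths are 75 nt for Snord1b, 131 nt for Scarna8 and 105 nt for Mir3062. Within each gene the values above 0 had a coefficient of variation of at most 0.0499 after division by each library's value of 1 fragment.

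No gene that is not a small RNA passed in the lower direction. The smallest unadjusted p among lower genes belonged to Hsph1, a cytosolic chaperone of the HSP110 family, with 42.8 ± 2.90 FPKM in B16F1 and 25.3 ± 0.0498 FPKM in B16F1-CXCL5 tumors and a limma adjusted p of 0.0674. It passed with library weights (log2 fold change -0.73, adjusted p = 0.0439). The other 9 genes of smallest p were Mettl16, Gas7, Sh3bp5, Ccl17, Procr, Gjb2, Map2k3, Abhd6 and Gja3, with log2 fold changes from -0.96 for Ccl17 to -0.38 for Map2k3 and limma adjusted p-values from 0.106 to 0.205. Among them Ccl17, a chemokine of dendritic cells, had 1.77 ± 0.276 and 0.423 ± 0.0826 FPKM, and Gjb2, a gap junction protein, had 97.1 ± 4.99 and 65.0 ± 7.22 FPKM.

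The count of 17 genes depended on single libraries, as 3 genes passed without B16F1-CXCL5 library 1, 2 without B16F1-CXCL5 library 2, 11 without B16F1 library 2 and 34 without B16F1 library 3. It was 8 with a pseudocount of 0.1, 7 with a mean FPKM of at least 3, 39 without the intensity trend and 31 with library weights. Each of the 14 genes lost its call without at least 1 library, Csf3r only without B16F1-CXCL5 library 2 (limma adjusted p = 0.0635), and all kept their direction. With every library kept, Csf3r, Mmp9, Srgn and Art5 kept their calls in each alternative setting, and the other 10 lost theirs in at least 1. S100a8 and Retnlg lost it in 5 such settings each, both also at the same sum per library, where the adjusted p of Retnlg was 0.0636, and Cxcr2 lost it in 4 (adjusted p from 0.0525 to 0.0934).

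The list of neutrophil markers rose as a group. Of its 29 tested members, 26 had a positive log2 fold change, 8 rose and 21 did not pass over all genes, and 22 rose when adjusted over the list alone. The median log2 fold change was 1.27, and the camera adjusted p was 2.98e-34 with the preset correlation. That call was lost in the stricter test (adjusted p = 0.244 with an estimated correlation), and fry gave an adjusted p of 0.0588 for 1 direction and 0.00185 for change in either direction. Fry in either direction passed for 9 lists, some of which camera did not call. These included myeloid suppressor genes (fry adjusted p = 0.000492), dendritic cell markers and apoptosis genes (fry adjusted p = 0.00561 for each). The neutrophil score was 1.41, 1.67 and 2.24 in the B16F1 libraries and 3.52 and 3.36 in the B16F1-CXCL5 libraries, with an exact two-sided permutation p of 0.1, the smallest possible. The members without a rise included Stfa1, Stfa2 and BC100530, with negative log2 fold changes of -0.28, -0.17 and -0.45, named after their values were seen. Of the 29 tested markers, 8 reached an FPKM of 1 only in B16F1-CXCL5 libraries, and without the filter the median was 1.24. Of 15 genes fixed for neutrophil granule proteins, 8 passed the expression filter. Mmp9, which is on both lists, rose over all genes and the other 7 did not pass, while all 8 had a positive log2 fold change and 6 rose when adjusted over the list alone (camera adjusted p = 1.52e-09, and adjusted p = 0.436 with an estimated correlation). The median was 0.68, and 0.31 without the filter (camera adjusted p = 2.39e-06). Mmp8, the neutrophil collagenase, had 0.389 ± 0.219 and 1.61 ± 0.1804 FPKM and reached an FPKM of 1 only in the B16F1-CXCL5 libraries. Lcn2, the siderophore-binding lipocalin of granules, had 3.18 ± 0.605 and 6.93 ± 2.42 FPKM.

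**Figure D2:**
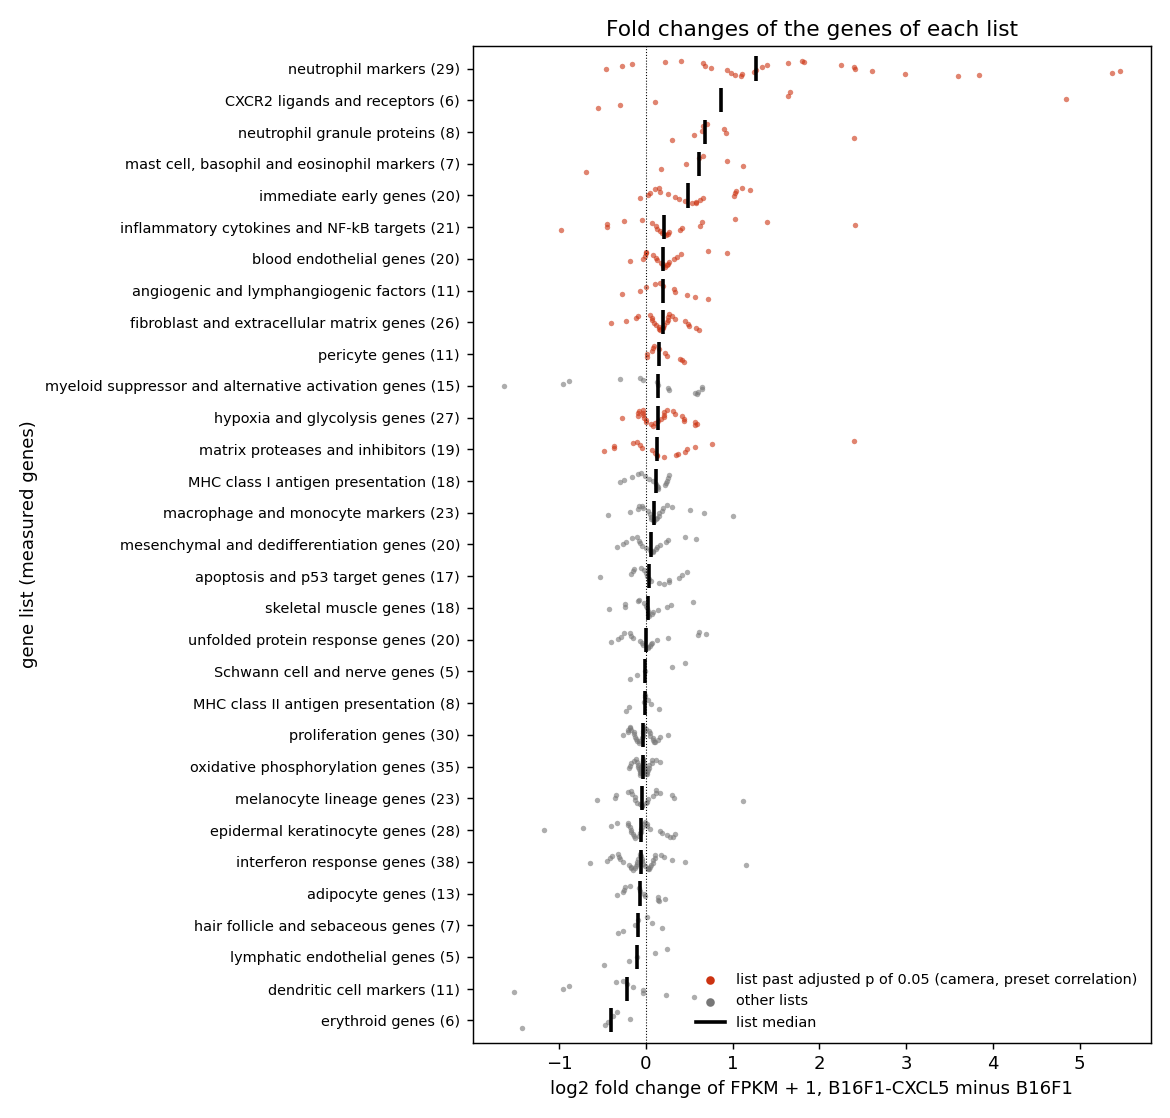
Log2 fold change of FPKM + 1, B16F1-CXCL5 minus B16F1, for each tested gene of 31 lists, with 1 point per gene, a black bar at the list median and red for lists past an adjusted p of 0.05 with camera's preset correlation. Neutrophil markers have the highest median, 1.27, and erythroid genes the lowest, -0.41. No list passed with an estimated correlation.

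Among the CXCR2 ligands and receptors, Cxcl5 and Cxcr2 rose over all genes and 4 of 6 tested members did not pass, while 3 rose when adjusted over the list alone. The camera adjusted p was 0.00208 with the preset correlation, and adjusted p = 0.517 with an estimated correlation. Without B16F1-CXCL5 library 1 the preset adjusted p was 0.051. The list holds Cxcl5, whose rise the engineering of the cells brings about. Without Cxcl5, a test added after the data were seen, the list did not pass, with a median log2 fold change of 0.10 over 5 members, 3 of them positive (camera adjusted p = 0.0765, and adjusted p = 0.763 with an estimated correlation). This reduced list passed without B16F1 library 3 (camera adjusted p = 0.0215, and adjusted p = 0.541 with an estimated correlation). Its median was -0.74 without B16F1-CXCL5 library 1 and 1.05 without B16F1-CXCL5 library 2. Cxcl2, another CXCR2 ligand, had 1.06 ± 0.762 and 5.24 ± 0.379 FPKM with a limma adjusted p of 0.263, and it passed without B16F1 library 3 (adjusted p = 0.043) and with replicate numbers as a block (adjusted p = 0.0305). Both settings compare the same libraries, with a log2 fold change of 1.94 in each. Cxcl1 had 1.88 ± 1.65 and 2.41 ± 2.77 FPKM, and Ppbp, a platelet chemokine, had 2.05 ± 1.11 and 1.01 ± 0.361 FPKM.

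Inflammatory cytokines and NF-kB targets rose as a list with a median log2 fold change of 0.21 (camera adjusted p = 0.000226, and adjusted p = 0.643 with an estimated correlation). In the main setting 0 of its 21 tested members passed limma over all genes, and 3 rose when adjusted over the list alone. The list score overlapped between groups, at 2.96 in B16F1-CXCL5 library 2 and 3.02 in B16F1 library 2 (exact two-sided permutation p = 0.3). Without B16F1-CXCL5 library 1 the list's camera adjusted p was 0.589. Il1b, also a neutrophil marker, had 4.48 ± 2.43 and 27.0 ± 9.38 FPKM with a limma adjusted p of 0.205. The macrophage inflammatory chemokines Ccl3 and Ccl4 had 2.46 ± 0.623 and 7.96 ± 0.0266 FPKM, and 2.38 ± 0.158 and 5.87 ± 0.572 FPKM. Ccl4 passed over all genes without the intensity trend (adjusted p = 0.0344), with library weights (adjusted p = 0.0403) and without the small RNA genes (adjusted p = 0.0476), the last of these chosen after the data were seen. Nfkbiz, an NF-kB regulator, had 3.37 ± 0.169 and 4.77 ± 0.707 FPKM. Immediate early genes rose as a list as well, with 19 of 20 tested members positive and a median of 0.49 (camera adjusted p = 1.52e-09, and adjusted p = 0.244 with an estimated correlation). Of these, 0 passed over all genes with limma and 7 rose when adjusted over the list alone. Atf3 had 7.82 ± 1.19 and 12.86 ± 0.464 FPKM, Jun 16.4 ± 2.29 and 24.8 ± 0.252 FPKM, Junb 28.6 ± 3.11 and 44.8 ± 9.38 FPKM, and Dusp1 15.5 ± 4.56 and 32.2 ± 6.74 FPKM.

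Vessel-related lists had small positive shifts. Blood endothelial genes had a median log2 fold change of 0.20 with 15 of 20 tested members positive (camera adjusted p = 0.000226, and adjusted p = 0.643 with an estimated correlation). Over all genes, 0 of them passed limma, and 1 rose when adjusted over the list alone. This was Esm1, a proteoglycan of endothelial tip cells, with 6.73 ± 1.46 and 13.7 ± 1.51 FPKM. Apln, the apelin peptide of sprouting vessels, had 5.26 ± 0.395 and 9.45 ± 2.82 FPKM, Kdr 2.61 ± 0.185 and 3.78 ± 0.653 FPKM, Flt1 1.78 ± 0.147 and 2.57 ± 0.349 FPKM, and Pecam1 10.4 ± 1.24 and 12.1 ± 1.95 FPKM. Pericyte genes had a median of 0.15 with 11 of 11 members positive (camera adjusted p = 0.0125, and adjusted p = 0.643 with an estimated correlation). Their score overlapped between groups, at 2.84 in B16F1 library 3 and 2.79 in B16F1-CXCL5 library 1 (exact two-sided permutation p = 0.3). Rgs5 had 10.5 ± 1.56 and 14.1 ± 2.10 FPKM, Abcc9 1.53 ± 0.288 and 2.37 ± 0.336 FPKM, and no pericyte gene passed over all genes or over the list alone. Angiogenic and lymphangiogenic factors had a median of 0.19 over 11 members (camera adjusted p = 0.0102, and adjusted p = 0.517 with an estimated correlation). Vegfa had 38.3 ± 7.13 and 56.8 ± 9.29 FPKM, and Angpt2 had 15.3 ± 1.53 and 19.3 ± 0.588 FPKM, with 0 members passing over all genes or over the list alone. The scores of the blood endothelial and angiogenic lists did not overlap between groups (exact two-sided permutation p = 0.2 for each). Leaving out B16F1 library 2 ended the camera calls of the pericyte list (adjusted p = 0.146) and the angiogenic list (adjusted p = 0.0721). The pericyte call was also lost without B16F1 library 1 (adjusted p = 0.058) and with a mean FPKM of at least 3 (adjusted p = 0.161).

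Hypoxia and glycolysis genes had a median log2 fold change of 0.13 over 27 members (camera adjusted p = 0.00481, and adjusted p = 0.977 with an estimated correlation), and 0 members passed over all genes or over the list alone. Their score overlapped between groups, at 6.77 in B16F1 library 1 and 6.54 in B16F1-CXCL5 library 1 (exact two-sided permutation p = 0.4). Ankrd37 had 12.99 ± 1.72 and 19.9 ± 0.787 FPKM and Ddit4 64.1 ± 3.42 and 81.3 ± 6.41 FPKM, and the camera call was lost without B16F1 library 2 (adjusted p = 0.499) or B16F1-CXCL5 library 2 (adjusted p = 0.623). Fibroblast and extracellular matrix genes had a median of 0.19 over 26 members (camera adjusted p = 0.0141, and adjusted p = 0.977 with an estimated correlation), and 0 members passed over all genes or over the list alone. Their highest score was that of B16F1 library 3, 5.20, against 4.96 and 4.80 in the B16F1-CXCL5 libraries (exact two-sided permutation p = 0.7). Col1a1 had 395 ± 160 and 579 ± 94.3 FPKM, and the median was -0.05 without B16F1 library 2. That call was also lost without B16F1 library 1 (adjusted p = 0.111) or B16F1-CXCL5 library 1 (adjusted p = 0.213), and when the libraries were rescaled to the same sum (adjusted p = 0.0873) or upper quartile (adjusted p = 0.084), or left unfiltered (adjusted p = 0.0509). Matrix proteases and inhibitors had a median of 0.12 over 19 members (camera adjusted p = 0.0366, and adjusted p = 0.918 with an estimated correlation). Their score also overlapped, at 4.24 in B16F1 library 3 and 4.075 in B16F1-CXCL5 library 2 (exact two-sided permutation p = 0.4). Only Mmp9 passed in that list, over all genes and over the list alone, and Adamts1 had 29.9 ± 8.45 and 43.4 ± 2.24 FPKM. The median was -0.17 without B16F1-CXCL5 library 1 (camera adjusted p = 0.672), and the call was lost without B16F1 library 2 (adjusted p = 0.487) and under 4 other settings (adjusted p from 0.0519 to 0.138). Mast cell, basophil and eosinophil markers had a median of 0.61 over 7 members (camera adjusted p = 0.0132, and adjusted p = 0.643 with an estimated correlation, 0.0611 at the same sum per library and 0.0507 at the same upper quartile). Over all genes 0 of them passed limma, while 1 rose and 1 fell when adjusted over the list alone. The higher one was Kit, a receptor of mast cells that melanocytes also use, with 9.25 ± 1.52 and 21.1 ± 3.11 FPKM. The lower one was Ear2, a ribonuclease of eosinophils, with 3.89 ± 0.694 and 2.02 ± 0.475 FPKM. The mast cell proteases Cpa3 and Mcpt4 had 1.65 ± 0.925 and 3.81 ± 0.151 FPKM, and 4.08 ± 2.00 and 6.58 ± 0.559 FPKM.

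The remaining 19 tested lists did not pass with either correlation with all libraries, and none of their members passed limma over all genes. Melanocyte lineage genes, which mark the tumor cells, had a median log2 fold change of -0.05 over 23 members (camera adjusted p = 0.909). Of these members, which include Kit, 1 rose and 0 fell when adjusted over the list alone. Without B16F1 library 3 the melanocyte list passed downward (median -0.19, adjusted p = 0.0154). Pmel had 2365 ± 443 and 2113 ± 367 FPKM, Tyr 228 ± 64.9 and 223 ± 21.8 FPKM, Mlana 2297 ± 358 and 2462 ± 71.7 FPKM, and Dct 3198 ± 504 and 3033 ± 156 FPKM. Macrophage and monocyte markers had a median of 0.10 over 23 members (camera adjusted p = 0.1). They passed upward without B16F1-CXCL5 library 2 (median 0.41, adjusted p = 1.44e-07), without B16F1 library 3 (median 0.22, adjusted p = 0.000757), with library weights (adjusted p = 0.0174) and with a mean FPKM of at least 3 (adjusted p = 0.0383). Their median was -0.18 without B16F1-CXCL5 library 1 and -0.06 without B16F1 library 2. Lyz2 had 211 ± 51.1 and 221 ± 76.6 FPKM, C1qb 68.3 ± 14.02 and 74.4 ± 20.8 FPKM, Csf1r 10.6 ± 2.92 and 12.4 ± 2.24 FPKM, and Adgre1, listed under its older name Emr1, 8.45 ± 2.76 and 9.69 ± 3.49 FPKM. Dendritic cell markers had a median of -0.22 over 11 members (camera adjusted p = 0.1), with 1 higher and 2 lower when adjusted over the list alone. They passed downward without B16F1-CXCL5 library 2 (adjusted p = 0.0399) and with each of the 3 rescalings (adjusted p from 0.0232 to 0.0382). Fscn1, an actin-bundling protein of mature dendritic cells that tumor cells can also make, had 75.7 ± 13.1 and 26.6 ± 11.3 FPKM with a limma adjusted p of 0.26. Clec10a had 9.997 ± 1.76 and 8.10 ± 0.481 FPKM. Myeloid suppressor and alternative activation genes had a median of 0.14 (camera adjusted p = 0.388), with 0 higher and 2 lower when adjusted over the list alone. They passed upward without B16F1-CXCL5 library 2 (median 0.29, adjusted p = 0.0197). Arg1 had 8.79 ± 2.43 and 11.8 ± 10.3 FPKM, Nos2 0.373 ± 0.168 and 0.628 ± 0.113 FPKM, and Tgfb1 22.1 ± 1.92 and 26.5 ± 0.0393 FPKM.

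Interferon response genes had a median log2 fold change of -0.06 (camera adjusted p = 0.388), although Cxcl10 had 46.7 ± 13.7 and 109 ± 52.9 FPKM, with a limma adjusted p of 0.465, and Bst2 had 140 ± 3.07 and 136 ± 40.5 FPKM. The list passed downward without B16F1-CXCL5 library 1 (median -0.21, adjusted p = 0.000573). MHC class I genes had a median of 0.12 (camera adjusted p = 0.267), with B2m at 692 ± 55.2 and 761 ± 43.0 FPKM and H2-D1 at 150 ± 21.1 and 162 ± 15.9 FPKM. MHC class II genes had a median of -0.01 (camera adjusted p = 0.857), with Cd74 at 123 ± 33.5 and 119 ± 4.81 FPKM and H2-Aa at 65.9 ± 17.7 and 65.5 ± 1.58 FPKM. Proliferation genes had a median of -0.03 (camera adjusted p = 0.48). Pcna had 323 ± 19.8 and 319 ± 37.2 FPKM, Rrm2 169 ± 13.97 and 179 ± 13.6 FPKM, and Mki67 28.7 ± 0.443 and 34.7 ± 3.39 FPKM. Apoptosis and p53 target genes had a median of 0.04 (camera adjusted p = 0.267), with Bax at 161 ± 2.67 and 163 ± 11.8 FPKM and Cdkn1a at 65.9 ± 6.05 and 79.6 ± 13.99 FPKM. When adjusted over the apoptosis list alone, 1 member rose and 1 fell. Oxidative phosphorylation genes had a median of -0.04 (camera adjusted p = 0.267), with Atp5b at 1213 ± 17 and 1058 ± 5.63 FPKM, and they passed downward without B16F1-CXCL5 library 1 (median -0.07, adjusted p = 0.046). Unfolded protein response genes had a median of 0.00 and a positive mean of 0.03, against a camera direction of down (adjusted p = 0.857). Calr had 547 ± 31.8 and 487 ± 55.7 FPKM and Hspa5 458 ± 26.3 and 417 ± 93.1 FPKM. When adjusted over this list alone, 1 member rose and 1 fell. Mesenchymal and dedifferentiation genes had a median of 0.05 (camera adjusted p = 0.617), with Vim at 1536 ± 144 and 1375 ± 7.59 FPKM and Cd44 at 156 ± 29.7 and 160 ± 2.98 FPKM. Without B16F1 library 3, the MHC class I list (median 0.15, adjusted p = 0.018), the MHC class II list (median 0.20, adjusted p = 0.0281) and the mesenchymal list (median 0.11, adjusted p = 0.0102) passed upward with camera. Without B16F1-CXCL5 library 2, the apoptosis list (median 0.18, adjusted p = 0.00369) and the unfolded protein response list (median 0.12, adjusted p = 0.00969) passed upward, and the latter passed downward without B16F1-CXCL5 library 1 (median -0.24, adjusted p = 0.00509).

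Besides the blood endothelial, pericyte and fibroblast lists above, lists for tissue around or within the tumor did not pass camera with all libraries. Lymphatic endothelial genes had a median log2 fold change of -0.11 over 5 members (camera adjusted p = 0.857). Pdpn had 30.6 ± 3.44 and 21.6 ± 3.29 FPKM, Nrp2 11.7 ± 0.955 and 11.3 ± 5.50 FPKM, Lyve1 6.44 ± 2.62 and 5.32 ± 1.45 FPKM, and Prox1 0.887 ± 0.170 and 0.849 ± 0.0223 FPKM. Keratinocyte genes had a median of -0.06 (camera adjusted p = 0.909), with Krt14 at 141 ± 98.1 and 96.8 ± 17.1 FPKM and Krt10 at 156 ± 93.7 and 142 ± 44.8 FPKM. The keratinocyte score of B16F1 library 3 was the highest, and without that library the median was 0.29 (camera adjusted p = 2.71e-08). Skeletal muscle genes had a median of 0.02 (camera adjusted p = 0.857), with scores of 6.58 in B16F1 library 3 and 6.25 in B16F1-CXCL5 library 2 against 4.96 to 5.11 in the other libraries. Their median ran from -0.66 without B16F1-CXCL5 library 2 to 0.69 without B16F1-CXCL5 library 1, each past the camera threshold (adjusted p = 0.000968 and 0.000351), and it was 0.48 without B16F1 library 3 (adjusted p = 0.000385). Acta1 had 421 ± 302 and 393 ± 206 FPKM. Hair follicle and sebaceous genes had a median of -0.09 (camera adjusted p = 0.949), with Krt17 at 39.1 ± 22.5 and 27.9 ± 2.36 FPKM, and passed upward without B16F1 library 3 (median 0.18, adjusted p = 0.0154). Adipocyte genes had a median of -0.07 (camera adjusted p = 0.857), with Fabp4 at 130 ± 27.7 and 114 ± 22.5 FPKM. Schwann cell and nerve genes had a median of -0.01 and a positive mean of 0.09 (camera adjusted p = 0.621), with Mbp at 68.3 ± 25.5 and 80.2 ± 6.57 FPKM. Erythroid genes had a median of -0.41 over 6 members (camera adjusted p = 0.25). The median was -0.82 without B16F1 library 2, where the list passed downward (adjusted p = 0.0194), and 0.14 without B16F1 library 1. Their score was 7.08 in B16F1 library 1 and 5.33 to 5.87 in the other libraries, and Hba-a1 had 240 ± 181 and 158 ± 23.3 FPKM.

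Most genes of lymphocytes were close to the detection limit in both groups. Of the T cell markers 2 passed the expression filter, Thy1 with 24.0 ± 9.23 and 21.5 ± 4.04 FPKM and Tcf7 with 6.72 ± 0.997 and 4.98 ± 0.630 FPKM, and both are also made by cells that are not T cells. Cd3e had 0.2999 ± 0.166 and 0.430 ± 0.177 FPKM, and Cd8a had 0.0996 ± 0.00901 and 0.140 ± 0.0398 FPKM. Of the cytotoxic and NK cell genes 2 passed the filter, Ccl5 with 9.06 ± 0.968 and 13.1 ± 8.70 FPKM and Gzmc with 1.13 ± 0.562 and 0.797 ± 0.310 FPKM. Gzmb had 0.206 ± 0.0854 and 0.365 ± 0.295 FPKM, and Ncr1 had 0.122 ± 0.140 and 0.142 ± 0.0551 FPKM. Of the B cell and plasma cell markers 0 passed, and Cd79a had 0.683 ± 0.384 and 0.749 ± 0.184 FPKM. Of the regulatory T cell and checkpoint genes 4 passed the filter, among them Cd274, the PD-L1 gene, with 3.31 ± 0.705 and 5.55 ± 1.88 FPKM and a limma adjusted p of 0.529. These 4 lists had too few members over the filter to be tested. Without the filter, the T cell list passed upward with a median log2 fold change of 0.07 over 20 members (camera adjusted p = 0.0149, and adjusted p = 0.896 with an estimated correlation). The other 3 did not pass there (adjusted p from 0.157 to 0.243), and 0 members of the 4 lists passed over all genes or when adjusted over the list alone.

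Across all tested genes the libraries were close to one another. Pearson correlations of log2(FPKM + 1) across genes were 0.969 to 0.980 within groups and 0.970 to 0.9754 between groups, and genes are not independent replicates. The first principal component held 30.7% of the variance and ran from B16F1 library 1 at -22.8 to B16F1 library 3 at 29.1, with both B16F1-CXCL5 libraries between. The second held 30.3% and separated the groups, with the B16F1 libraries at -18.0 to -9.82 and the B16F1-CXCL5 libraries at 16.3 and 23.9.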

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

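The tests without the small RNA genes and of the CXCR2 list without Cxcl5, and all alternatives for the neutrophil score and the library correlations, were chosen after the results were seen. The Cxcl5 log2 fold change was 5.40 with a pseudocount of 0.1 (adjusted p = 0.0556, against 0.00118 to 0.235 over all alternatives) and 4.56 to 5.16 when each library was left out in turn, and it stayed positive in all of these settings. The count of 17 genes was 8 with a pseudocount of 0.1, 7 with a mean FPKM of at least 3, 39 without the intensity trend, 31 with library weights and 2 to 34 without single libraries (2 without B16F1-CXCL5 replicate 2, 34 without B16F1 replicate 3). It was 24, all higher, without the small RNA genes, 14 of them among the 17. Leaving out a B16F1-CXCL5 replicate leaves 1 library in that group, which is then assumed to vary like the B16F1 libraries. The count of 12 lists was 0 with an estimated correlation, 0 with fry in 1 direction, 9 with fry in either direction, and 8 to 20 without single B16F1 libraries. It was 11 with Cxcl5 taken out of the CXCR2 list, which then did not pass (adjusted p = 0.0765, against 0.00208). That reduced list passed without B16F1 replicate 3 (camera adjusted p = 0.0215), and its median ran from -0.74 to 1.05 as single libraries were left out. The count of lists was 11 of 35 without a filter, where the T cell list passed (adjusted p = 0.0149). Leaving out single libraries turned the direction that camera gave for 5 lists that passed with or without the library. Medians of other lists changed sign too, for example to -0.18 for macrophage markers and -0.17 for matrix proteases without B16F1-CXCL5 replicate 1. Fibroblast genes ran from -0.0469 (without B16F1 replicate 2) to 0.473, keratinocyte genes from -0.28 to 0.29 (without B16F1 replicate 3, adjusted p = 2.71e-08) and MHC class II genes from -0.15 to 0.20 (without B16F1 replicate 3, adjusted p = 0.0281). Muscle genes ran from -0.66 (without B16F1-CXCL5 replicate 2, adjusted p = 0.000968) to 0.69, and unfolded protein response genes from -0.24 to 0.12 (without B16F1-CXCL5 replicate 2, adjusted p = 0.00969). Apart from the libraries left out, the cause of these changes was not tested. The difference of the neutrophil score between groups, 1.67, was 2.31 with a pseudocount of 0.1. The mean correlation between libraries, 0.974, was 0.957 and 0.970 with pseudocounts of 0.1 and 0.5, 0.986 without a filter, 0.962 with a mean FPKM of at least 3, 0.971 with the same sum and 0.985 without small RNA genes. Of the named genes other than Cxcl5, none changed sign with a call on either side, 70 calls were lost and 10 gained over all alternatives. No alternative scaling moved the median of all genes by 0.1.

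The labels state no pairing of libraries by replicate number, and only 2 numbers are shared. The deviations of libraries 1 and 2 correlated at -0.03 and -0.02 with those of the same number. With 2 B16F1-CXCL5 libraries the deviations mirror each other, so these correlations cannot show whether libraries were handled in pairs. With the replicate number as a block the counts were 46 genes, 42 of them higher, and 22 lists, with medians of 0.29 for keratinocyte, 0.20 for MHC class II and 0.13 for adipocyte genes. B16F1 replicate 3 then has no partner, and the medians of keratinocyte and MHC class II genes equal those without it. Cxcl5 had 4.56 with the block.

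Depth was estimated at 26600000 to 28600000 fragments per library. At this design 28.4% of simulated 1.5-fold changes, 76.2% of 2-fold changes and 97% of 4-fold changes were called. The simulated genes varied independently of one another, and no other number of libraries was simulated. Each simulation changed more genes than the 17 called here, with spread from limma's own model, so the shares called may be too high for the real data.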

Other observations

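The tests of tumor cell share, blood, epidermis and single fragments came after the results were seen. So did the choice of genes in the paragraph on granule genes. The heat-shock protein genes Hspa8, Hspa4, Dnaja1, Hsp90aa1, Hspa1a and Hspa1b were also chosen after the results were seen. The chaperone partner genes and the other splits of the libraries were tested as fixed before their values were seen.

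Some granule genes that neutrophils transcribe during their development in the marrow had very low values in both groups, unlike Lcn2 of the same list at 3.18 and 6.93 FPKM. Elane had 0.0196 and 0.0602 FPKM as B16F1 and B16F1-CXCL5 means, Mpo was listed at 0 in all 3 B16F1 libraries with a mean of 0.00815 in the others, and Camp had 0.0928 and 0.0458, Ngp 0.012 and 0.0338, and Ltf 0.00468 and 0.115 FPKM, each under the expression filter, while Mmp8 had 0.389 and 1.61 FPKM. Trem1, an activating receptor of neutrophils, had 0.0990 and 1.36 FPKM, Hdc, the histamine-forming decarboxylase, 0.721 and 4.90 FPKM, and the acid receptor Hcar2, listed as Niacr1, 1.63 and 15.04 FPKM. Their limma adjusted p-values were 0.106, 0.0674 and 0.106, so they did not pass over all genes. On the opposite side stood Retnla, a gene of alternatively activated macrophages, at 21.5 and 6.05 FPKM, Ccl17 at 1.77 and 0.423 FPKM and Ccl22 at 2.70 and 1.00 FPKM, with limma adjusted p-values of 0.332, 0.181 and 0.55.

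The rise of neutrophil genes was weighed against changes in tissue composition, with bootstrap intervals over genes of the difference between list medians. These intervals measure the spread between genes and not between tumors. They treat genes as independent, although camera estimated correlations of 0.731, 0.646 and 0.87 within the macrophage, erythroid and keratinocyte lists, so they may be too narrow. The list medians were already known, with that of the neutrophil list the highest of 31, so the signs of the differences were set in advance. Of the 29 neutrophil markers, 8 reached an FPKM of 1 only in B16F1-CXCL5 libraries, and without the filter their median was 1.24. A lower share of tumor cells would raise the markers of all host cells alike, but the neutrophil median exceeded the macrophage median by 1.17 on the log2 scale (95% interval 0.875 to 1.74). The melanocyte list had a median of -0.05, and of -0.19 without B16F1 replicate 3. More residual blood would raise erythroid genes as well, but the neutrophil median exceeded theirs by 1.67 (1.36 to 2.61). The erythroid median itself ran from -0.82 to 0.14 as single libraries were left out. Erythroid genes gauge the amount of blood and cannot tell how many neutrophils that blood held. More epidermis would raise keratinocyte genes as well, but the neutrophil median exceeded theirs by 1.33 (1.03 to 1.92). Each lower limit stayed above 0 when any 1 library was left out, the lowest being 0.615 for macrophages without B16F1-CXCL5 replicate 2. A hypothesis that these values allow is that the tumors overexpressing CXCL5 held more neutrophils, which was not tested independently. Other differences between the cell lines, such as those of a single clone, and a change of gene activity within neutrophils, remain open and untested.

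Of the 10 splits of the libraries into 3 and 2, 2 gave at least as many genes as the real split with its 17, the real one included, and the highest other split gave 26. That split sets B16F1 3 and B16F1-CXCL5 2, the libraries with the highest muscle scores, against the rest, and 10 splits are too few for a share under 0.05.

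The 3 called small RNA genes may be single fragments on genes shorter than a sequenced fragment. After division by the value of 1 fragment in each library, the highest coefficient of variation of their values above 0 was 0.0499, which counting error would reach only at about 402 fragments or more. For each gene these are only 2 or 3 values, all of a single group. Limma favours genes that vary little within a group, so the low variation was largely set by the selection and cannot decide the question. Over the small RNA genes of the table, 44.9% of 374 ratios between libraries from 1.5 to 4.5 lay within 0.1 of a whole number, where an even spread gives 20%. Of the genes with a mean FPKM over 10 and a 0 in some library, 50 of 51 were small RNA genes. No biological explanation was tested for these genes.

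Hsph1 was 1 of several heat-shock protein genes with lower values in the B16F1-CXCL5 tumors. Hspa8 had 1599 ± 76.2 and 1169 ± 31.0 FPKM, and Dnaja1 had 41.0 ± 3.28 and 31.4 ± 1.31 FPKM. Their limma adjusted p-values were 0.266 and 0.405. Differences were smaller for Hspa4 and Hsp90aa1, with log2 fold changes of -0.33 and -0.16 (limma adjusted p = 0.406 and 0.727). Hsph1 itself passed only with library weights (adjusted p = 0.0439, against 0.0674). To see whether this may be a shared decline, 20 partner genes of the cytosolic chaperones were fixed before their values were looked at. Their median log2 fold change was -0.18, with 16 of 20 below 0 and a camera p of 0.00012, but p = 0.14 with an estimated correlation and 0 members past the threshold over all genes. The median stayed negative, from -0.23 to -0.12, when each library was left out in turn, and the inducible Hspa1a and Hspa1b had log2 fold changes of 0.04 and -0.06. A small shared decline is consistent with these values, and whether it comes from the tumor cells, the mixture of cells or the handling of the tumors was not tested.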
